A study of Mus musculus with 4 samples.

How the data were processed

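RNA sequencing libraries were made from mouse E14tg2a embryonic stem cells 48 hours after transfection with a scrambled shRNA or an shRNA against the long non-coding RNA Mrhl, with 2 libraries per group. E14tg2a is an established mouse embryonic stem cell line. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase I and made into libraries with an Illumina TruSeq RNA kit. A label field names a lentivirus, while the treatment protocol describes transient transfection. Both replicates of a group were named as separate samples, and nothing in the labels says whether they came from separate cultures.

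The data analysed here were 2 tables, 1 of genes the authors listed as down-regulated and 1 of genes they listed as up-regulated. Each row gave a gene symbol, a gene type, a description and 1 signed fold-change value. The deposited fold change was handled as a score, because the authors' column headers do not state whether its scale is log2 or a signed linear fold. Values were given to at most 5 decimals, and none lay between -1.5 and 1.5. A value of -2 would stand for a 4-fold decrease on a log2 scale and for halving on a linear one, so no value was converted to another scale. TopHat2, Cuffdiff and the mm10 genome build are named in the submitters' processing notes. Their versions, the annotation, the test and the threshold behind the lists are not given in the sources used here.

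No value per library, read count, expression level or p-value was in the tables analysed. The depth of the libraries is therefore unknown, no replicate error can be attached to any value, and no test across replicates was possible. Each fold-change value below is the authors' value for sh-Mrhl against scrambled, and the tables do not state which libraries entered it. The test planned for counts or FPKM per library and the comparison of expression levels were not run for the same reason.

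Symbols were reduced to 1 per table, since 7 symbols in the lower table and 3 in the higher table were repeated with the same value. The symbol Tex16 was in both tables and was left out of tests of direction, which ran on 1131 symbols. Positions, strands and exonic lengths came from GENCODE M21 on GRCm38, the assembly also called mm10. Of 1132 distinct symbols, 1129 were found there, and 1121 had the same gene type in both sources. Where a symbol had several loci, the locus of matching gene type with the lowest start was used. The strand setting of the authors' counting is not given, so reads of overlapping genes on opposite strands may not be separable.

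For each list with at least 5 listed members, the split into lower and higher genes was compared with that of all other listed genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 10 lists tested. All 35 lists were fixed before the data were examined. The genes the authors tested but did not list were not used here, so enrichment of a list against all tested genes was not computed. Chromosomes with at least 10 listed genes were tested in the same way. Absolute values of lower and higher genes were compared by a two-sided permutation test of medians with 100000 resamples. Pairs of neighbouring listed genes less than 100 kb apart were tested for sharing a direction by permuting directions over genes, one-sided, with 100000 resamples. In all of these tests the unit is the gene, and genes are not independent replicates. The tests describe the lists and carry no information on the spread between libraries.

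Named genes followed a rule fixed before the data were examined, without the limits on q and FPKM that the tables did not allow. It takes the 10 largest values in each direction and up to 4 listed members of each gene list with the largest values. 1 gene that the rule names is not reported here. Other listed genes named were chosen after their values were seen, as said where they appear, apart from Tex16, named for being in both tables. The list tests were tested on simulated data, with directions drawn at random for the 1131 symbols in 1000 simulations. In 1.5% of sets without any effect at least 1 list was called. A list of 25 genes of which each had a 95% chance of being lower was called in 86.6% of simulations, and a list of 10 such genes in 0.0%. A list of 10 or fewer genes leaning lower was therefore not detectable at the adjusted threshold of 0.05. Lists leaning higher were not simulated. Alternatives raised the minimum absolute value to 2, left out unnamed gene models, counted every row, kept protein-coding genes only, or left out values from 1.9 to under 2. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.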

Results

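Transcript levels were compared between mouse embryonic stem cells that received an shRNA against Mrhl and cells that received a scrambled shRNA, with 2 libraries in each group, harvested 48 hours after transfection. Mrhl is a nuclear long non-coding RNA transcribed from within an intron of Phkb, which encodes the beta subunit of phosphorylase kinase. The comparison addresses which transcripts change when Mrhl is targeted in these cells. The tables hold the genes the authors listed as changed, with 1 signed fold-change value per gene, negative where the gene was lower in sh-Mrhl. The scale of these values is not stated, and they have no replicate error, p-value or depth. Values are therefore given as deposited, and a gene is called lower or higher only in the sense that the authors listed it so.

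The lists held 722 gene symbols lower in sh-Mrhl and 411 higher, so that 36.3% of the listed symbols with 1 direction were higher. The highest value belonged to the transcribed pseudogene C920009B18Rik, at 9.52 in the authors' deposited table, followed by the non-coding gene Gm27403 at 7.33. Among protein-coding genes, Six3, a homeobox regulator of forebrain and eye development, had the highest value in the authors' deposited table, 4.74. Six3 lies on chromosome 17 from 85613608 to 85629302 in mm10. The synaptonemal complex relative Sycp2l was at 4.32 in the authors' deposited table. The sodium-calcium exchanger gene Slc24a2 stood at 3.94, the sphingomyelinase-family gene Smpd5 at 3.81, the protocadherin gene Pcdh11x at 3.52, Ankef1 at 3.45 and the gene model Gm9962 at 3.38 in the authors' deposited table.

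On the lower side, the most negative values in the authors' deposited table were -4.81 for D130043K22Rik and -4.79 for the small nucleolar RNA gene Snord17. The pseudogene 4932431P20Rik followed at -4.32, the non-coding A430010J10Rik at -4.14, the small RNA gene Gm24407 at -4.12 and the cilium gene Cfap61 at -4.003 in the authors' deposited table. The remaining genes of the 10 most negative were Gm16425, Gm43913, 1810062O18Rik and Gm5451, with values from -3.98 to -3.79 in the authors' deposited table. Among further protein-coding genes, chosen after their values were seen, the authors' deposited table gave -3.67 for the lysosomal transporter gene Abcb9, -3.66 for the RNA-binding protein gene Rbms3 and -3.61 for Pink1, a kinase of mitochondrial quality control. Neither Mrhl nor Phkb was among the listed symbols. GENCODE M21 has no gene under the symbol Mrhl, and the sense-intronic gene model Hm629797, on chromosome 8 from 85994245 to 85996642 within Phkb, was not listed either. The level of the targeted RNA could therefore not be checked from these tables.

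**Figure D1:**
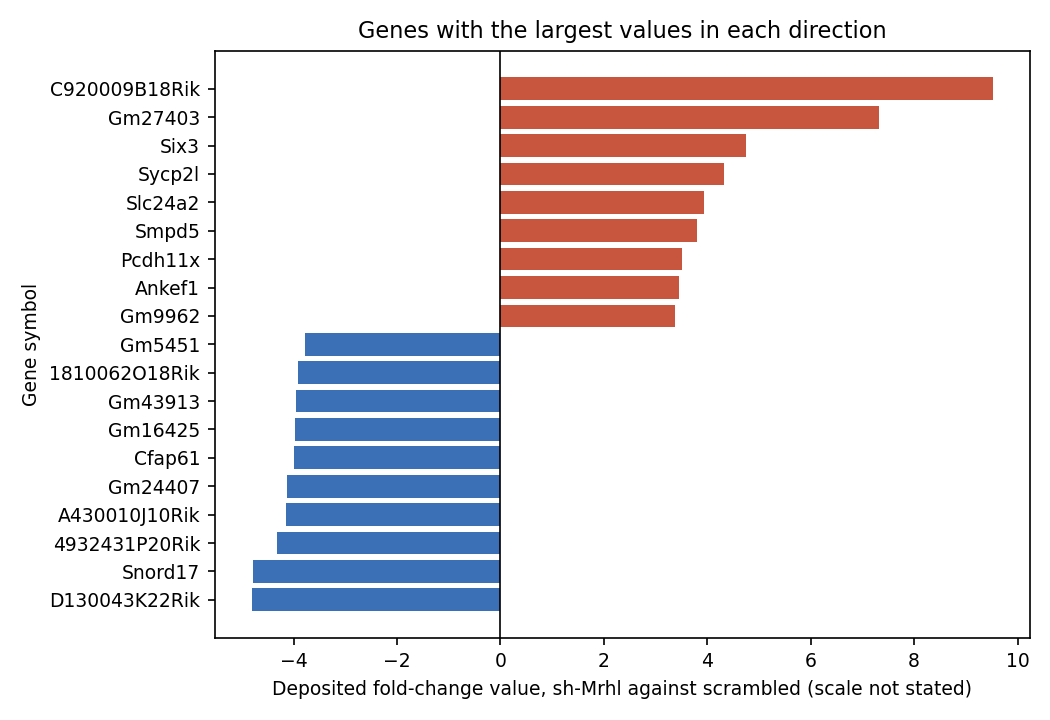
Horizontal bars show the deposited fold-change value (x axis, sh-Mrhl against scrambled, scale not stated) of the 10 lower genes and 9 of the 10 higher genes with the largest values, 1 bar per gene symbol (y axis), blue for lower and red for higher. C920009B18Rik (9.52) and Gm27403 (7.33) stand apart from the other genes drawn, whose absolute values lie between 3.38 and 4.81.

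Developmental regulators were listed in both directions. No expression level was available, so which of these values rest on few reads is unknown. The values alone do not show a change of lineage. Of the 54 annotated neuroectoderm and neural progenitor regulators on the list examined, 3 were higher and 1 was lower. The higher ones in the authors' deposited table were Six3, the neural POU-domain factor gene Pou3f2 at 2.46 and the Notch effector gene Hes5 at 1.96, while Foxp2, a forkhead factor gene of the developing brain, was at -2.50. Pou3f2 lies on chromosome 4 from 22482780 to 22488366 and Foxp2 on chromosome 6 from 14901349 to 15441977. Of the 58 mesoderm and cardiac or skeletal lineage genes, 3 were lower, namely Runx2, the osteoblast regulator, at -2.51, Dlx3 at -1.85 and the cardiac and trophoblast factor gene Hand1 at -1.70 in the authors' deposited table. Mesp1, a regulator of early cardiac mesoderm, was higher at 2.12 in the authors' deposited table. Among 40 endoderm genes, Apoa1, encoding an apolipoprotein, was at 2.81, the pancreatic regulator gene Pdx1 at 2.15 and Thbd, encoding thrombomodulin, at -1.86 in the authors' deposited table. Hand1 was also the 1 listed gene of 20 trophectoderm genes. The Hox genes were split 2 against 2, and the authors' deposited tables gave -3.32 for Hoxb7, -1.88 for Hoxc4, 2.44 for Hoxb8 and 1.95 for Hoxa9.

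A further list of 19 lineage transcription factors was drawn up from what was known of the study, so its direction is not independent evidence. It had 5 lower members and 1 higher member (two-sided Fisher's exact test against the other listed genes, p = 0.426, adjusted p = 0.618). A list of 10 leaning lower was already not detectable in simulations. The test of this smaller list therefore cannot tell whether it leans lower. Besides Runx2, Foxp2, Dlx3 and Hand1, its lower members included Erg, an ETS factor gene of endothelium, at -3.23 in the authors' deposited table, and its higher member was Pou3f2. The list of TGF-beta, BMP and Notch signalling had 2 lower and 3 higher members (adjusted p = 0.618, Fisher's exact test). In this list too a lean lower was not detectable, and a lean higher was not simulated. Dll4, a Notch ligand gene, was at 2.46 and Hes5 at 1.96, against -1.87 for the BMP signal transducer gene Smad9 and -1.85 for Heyl, another Notch effector gene, in the authors' deposited tables.

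Extracellular matrix and basement membrane genes were listed as lower in 10 of 10 cases. The authors' deposited table gave -2.97 for the brain matrix glycoprotein gene Tnr, -2.85 for Col15a1, -2.78 for the laminin chain gene Lamc3 and -2.76 for Col24a1. The other 6 were Col3a1 and, named after their values were seen, Col17a1, Col26a1, Col22a1, Matn4 and Col12a1. The split differed from that of the other listed genes at an unadjusted p of 0.0168 (two-sided Fisher's exact test) but not after adjustment over the 10 lists (adjusted p = 0.168). Collagen genes outside the fixed list, also chosen after their values were seen, included Col6a4 among the lower genes and Col6a6 among the higher ones, at 1.99 in the authors' deposited table. With all listed collagens added, 11 genes were lower and 1 was higher (p = 0.0655, adjusted p = 0.618, Fisher's exact test). Of the integrins, cadherins and other adhesion molecules, 6 were lower and 1 was higher (adjusted p = 0.618, Fisher's exact test). In the authors' deposited tables the synaptic adhesion gene Lrfn5 was at -3.26, the giant cadherin gene Fat2 at -2.15, Cdh7 at -2.003 and the tight junction gene Cldn11 at -1.86, and the higher member, named after its value was seen, was the hair cell cadherin gene Cdh23 at 1.74. Protocadherins had Pcdhb20 at -2.33 and Pcdh8 at -1.66 against Pcdh11x at 3.52 in the authors' deposited tables. Keratins had 2 lower and 3 higher members (adjusted p = 0.618, Fisher's exact test), with Krt15 at -2.78 and Krt12 at -1.83 against Krt1 at 3.34 and Krt79 at 1.86 in the authors' deposited tables. The adhesion and keratin lists are smaller than the matrix list, so a lean lower was not detectable in them. A lean higher was not simulated.

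Genes of neurons, channels and transporters were also split. Neuronal and synaptic genes had 4 lower and 3 higher members (adjusted p = 0.788, Fisher's exact test). The vesicular glutamate transporter gene Slc17a6 was at -3.53 and the neural adhesion gene Dscam at -2.10, while the postsynaptic scaffold gene Dlg2 was at 3.24 and the kainate receptor gene Grik2 at 1.73 in the authors' deposited tables. Ion channel subunits had 3 lower and 3 higher members (adjusted p = 0.788, Fisher's exact test). Both lists are too small for a lean lower to have been detectable. Scn4b, a sodium channel subunit gene, was at -3.52 and the potassium channel gene Kcnc1 at -2.42, against 1.98 for Kcnv2 and 1.96 for the muscle sodium channel gene Scn4a in the authors' deposited tables. Solute carriers had the most listed members among the named families examined, with 13 lower and 12 higher members (adjusted p = 0.618, Fisher's exact test). Slc24a2 and Slc24a3, both of the potassium-dependent sodium-calcium exchangers, were at 3.94 and 3.06, and Slc26a5, which encodes the hair cell motor protein prestin, was at 2.93 in the authors' deposited table. Olfactory and vomeronasal receptors had 8 lower and 4 higher members (adjusted p = 1, Fisher's exact test), led by Vmn2r27 at -2.39, Olfr1369-ps1 at -2.38, Olfr1494 at -2.34 and Olfr772 at -2.19 in the authors' deposited table. Members of such receptor families can share reads with close copies, so their single values are uncertain.

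**Figure D2:**
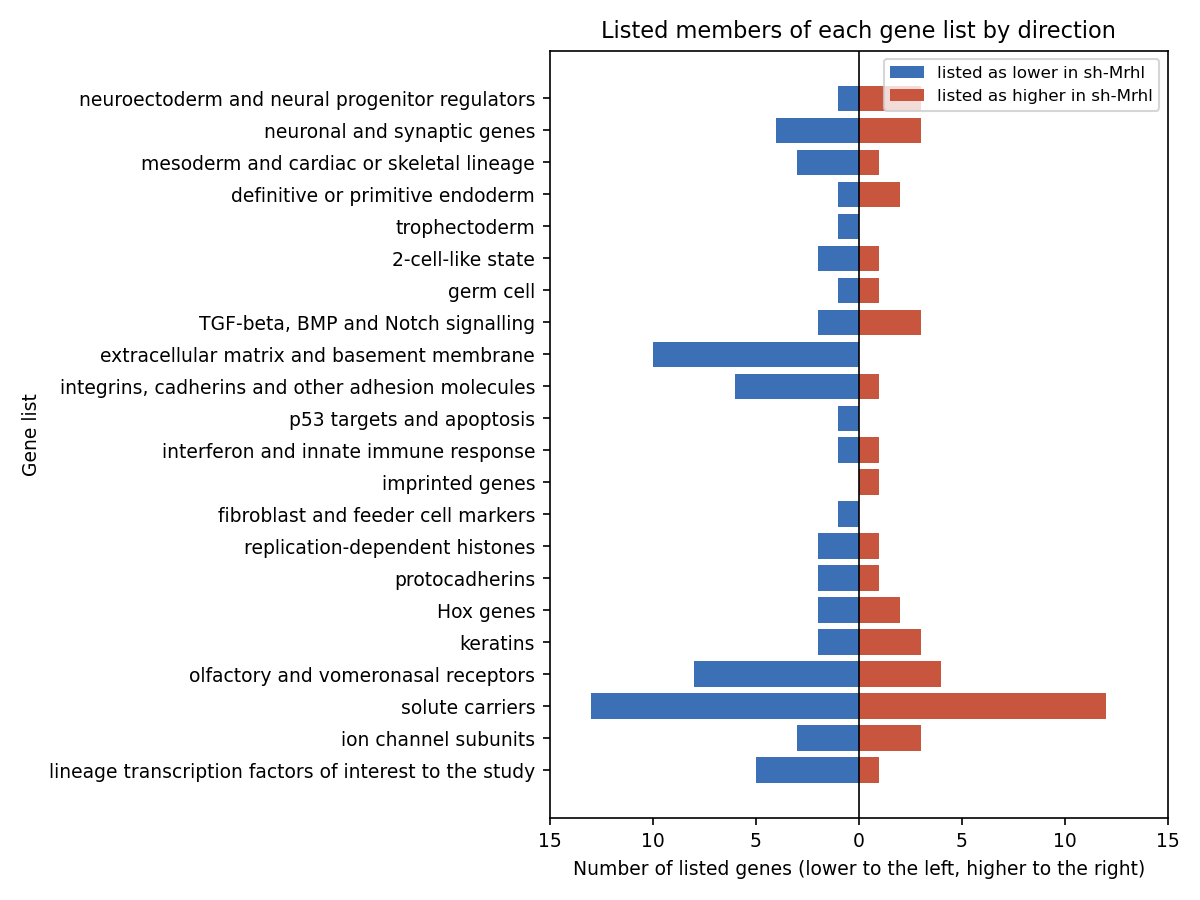
Bars give the number of listed genes (x axis) that were lower (blue, to the left) or higher (red, to the right) in sh-Mrhl for each gene list with at least 1 listed member (y axis), unnamed gene models left out. The 10 extracellular matrix genes were all lower, while the 25 solute carriers were split 13 to 12.

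No gene of the core and naive pluripotency list, which has 38 annotated members such as Nanog and Esrrb, was in either table. The same held for the 24 genes of the primed state, the 69 of Wnt signalling, the 61 of cell cycle and mitosis, and the 90 chromatin modifiers. It also held for the 48 genes of the unfolded protein and amino acid responses, 44 of glycolysis and hypoxia, 41 of cholesterol and fatty acid synthesis and 42 of the immediate early and heat shock responses. None of 89 ribosomal protein genes, 37 mitochondrially encoded genes or 416 Zfp-named zinc finger genes was listed. Over all annotated protein-coding symbols 549 of 21924, or 2.50%, were listed, so a short list can lack a listed member for that reason alone. Absence from the tables does not show that a gene was unchanged, since values of unlisted genes were not used here and the threshold is not stated.

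Some markers of other states or cell types were listed. Of 28 annotated genes of the 2-cell-like state, a rare embryonic stem cell state, 3 were listed. Zscan4f was at -3.47, Usp17la at -1.76 and Usp17lc at 2.06 in the authors' deposited tables, and all 3 have close copies that can share reads. Of 36 germ cell genes 2 were listed, with Tdrd6 at -2.84 and the meiotic cohesin gene Smc1b at 1.89 in the authors' deposited tables. Of 30 fibroblast and feeder cell markers only Col3a1 was listed, at -1.69 in the authors' deposited table. Interferon and innate immune genes had Usp18 at -1.83 and Iigp1 at 1.56, and the p53 and apoptosis list had the death receptor gene Fas at -1.85 in the authors' deposited tables. Among imprinted genes, Nap1l5 was at 1.87 in the authors' deposited table. Replication-dependent histones had Hist1h3i at -1.996, Hist1h2ab at -1.71 and Hist1h2br at 1.94 in the authors' deposited tables, again with close copies.

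Protein-coding genes made up 553 of the 1131 symbols with 1 direction, with 347 lower and 206 higher. The other types included processed pseudogenes, with 100 lower and 72 higher, and TEC models, with 83 lower and 22 higher. TEC models are transcript models still to be experimentally checked. Antisense genes were 60 lower and 35 higher, and lincRNA genes 58 lower and 36 higher. TEC models were lower more often than the other listed genes, at 79.0% against 62.2% (two-sided Fisher's exact test, adjusted p = 0.00764 over gene types with at least 5 genes, a family chosen after the data were seen). All 9 snoRNA genes (adjusted p = 0.199, Fisher's exact test) and all 6 snRNA genes (adjusted p = 0.332, Fisher's exact test) were lower. Unnamed gene models, with symbols of the Gm or Rik kind, made up 563 symbols, 367 lower and 196 higher (adjusted p = 0.618, Fisher's exact test).

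**Figure D3:**
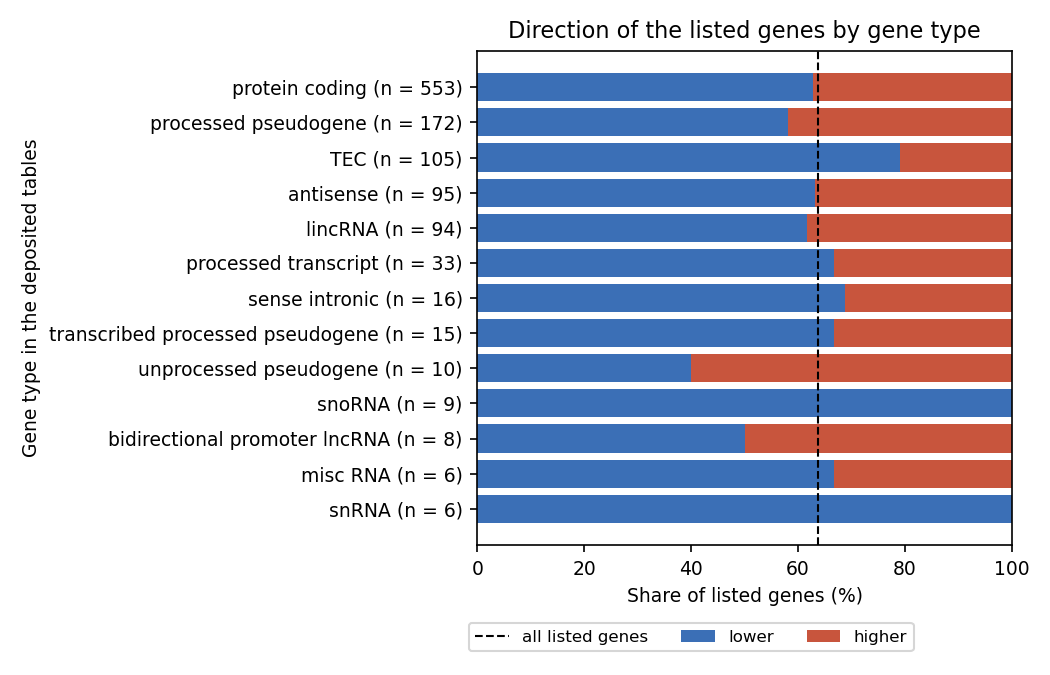
Stacked bars show the share of listed genes (x axis, %) that were lower (blue) or higher (red) in sh-Mrhl for each gene type with at least 5 listed genes (y axis, n genes), and the dashed line is the lower share over all listed genes. TEC models were 79.0% lower, and the 9 snoRNA and 6 snRNA genes were all lower.

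The median absolute value was 1.91 for lower and 1.94 for higher genes, a difference of -0.031 (two-sided permutation test across genes, p = 0.205). The upper quartile was 2.35 for lower and 2.17 for higher genes, and values of at least 2 were reached by 320 of 722 lower and 136 of 411 higher genes. These further differences in the distributions were not tested. The largest absolute value was 4.81 on the lower side and 9.52 on the higher side, that of C920009B18Rik. Values of at least 3 were reached by 46 lower and 25 higher genes. No chromosome differed from the rest in its split after adjustment over the 20 tested (smallest adjusted p = 0.255, Fisher's exact test), and 3 had an unadjusted p under 0.05. Of these, chromosome 14 had 16 lower and 19 higher genes (p = 0.0309, Fisher's exact test), chromosome 10 had 25 lower and 25 higher (p = 0.0493, Fisher's exact test) and chromosome 1 had 75 lower and 27 higher (p = 0.0396, Fisher's exact test). Neighbouring listed genes less than 100 kb apart shared a direction in 59 of 115 pairs, against 61.8 expected by permutation (p = 0.736, one-sided permutation test). The share lay above chance in 4 of 6 alternatives, among them 67.5% without unnamed gene models (p = 0.0461, one-sided permutation test). Among pairs chosen after their values were seen, Six3 and its overlapping opposite-strand transcript gene Six3os1 were both higher, as was Six2, 54974 bp from Six3, whereas Hoxb8 was higher and Hoxb7, 1307 bp away, was lower.

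**Figure D4:**
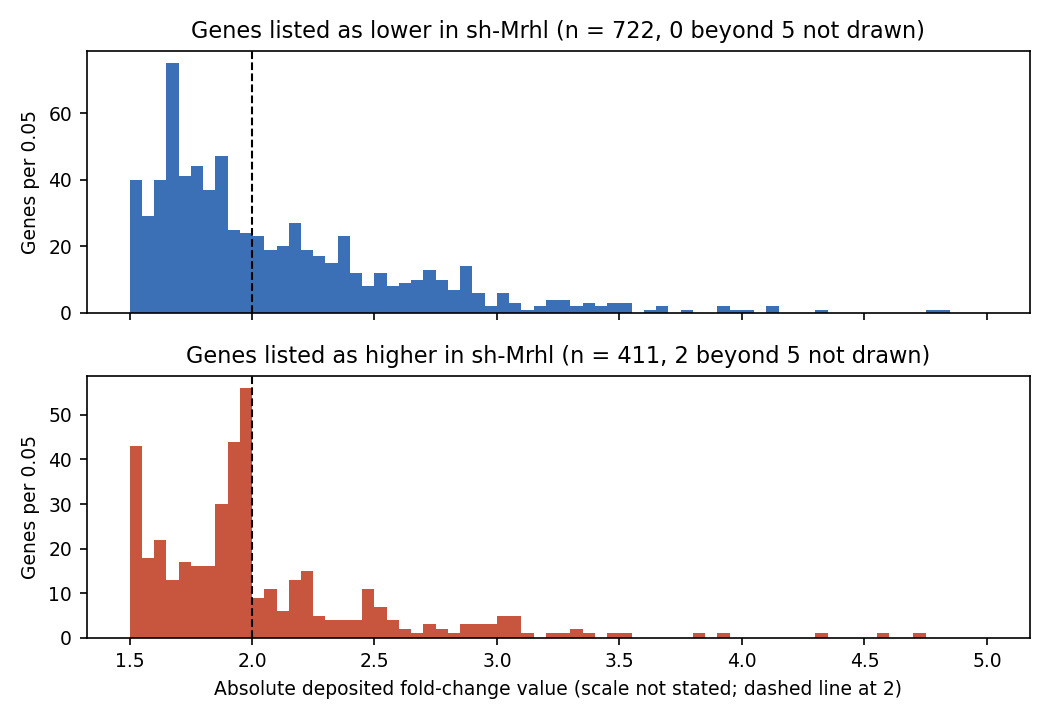
Histograms show the number of genes per 0.05 of absolute deposited fold-change value (x axis, scale not stated) for the 722 lower genes (upper panel) and the 411 higher genes (lower panel), with a dashed line at 2 and the 2 higher genes beyond 5 left out. In the higher genes, 100 values lie from 1.9 to under 2 and 20 from 2 to under 2.1, against 49 and 42 in the lower genes.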

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

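Leaving out values from 1.9 to under 2, keeping protein-coding genes only, counting every row and adding collagens were chosen after the data were seen. With absolute values of at least 2, 320 genes were lower and 136 higher, so that 29.8% were higher, and without values from 1.9 to under 2 the share was 31.6%. Without unnamed gene models 354 were lower and 214 higher, and with protein-coding genes only 347 and 206. None of the list directions run passed the adjusted threshold, but lists of 10 or fewer genes leaning lower were not detectable at it. Without unnamed gene models their own list could not be run, and collagens were added to the extracellular matrix list only. Over its alternatives, the adjusted p of the extracellular matrix list ranged from 0.145 to 0.656. A list of 10 leaning lower was not detectable at the adjusted threshold of 0.05, so this range does not show the absence of a lean. The direction of the ion channel list turned with values of at least 2 and without values from 1.9 to under 2 (adjusted p = 1 in both, Fisher's exact test). The difference in median absolute value turned to 0.011 without values from 1.9 to under 2 (permutation p = 0.718). The share of neighbouring pairs with 1 direction, 51.3% and below its chance value of 53.8%, rose above chance in 4 of 6 alternatives. It was 73.3% with values of at least 2 (permutation p = 0.175), 67.5% without unnamed gene models (p = 0.0461, the 1 value under 0.05), 60.6% with protein-coding genes only (p = 0.246) and 58.4% without values from 1.9 to under 2 (p = 0.423). It stayed below chance within 20 kb, at 43.6% (permutation p = 0.925), and with overlapping genes left out, at 51.9% (permutation p = 0.69). The chance value depends on the share of higher genes, so 53.8% holds for the main result only. Chance values and numbers of pairs are not given for the alternatives, so their percentages cannot be compared directly with it. The cause was not tested. No paired analysis was possible because the tables hold no values per library, and leaving out replicates, thresholds on q or FPKM, pseudocounts, other normalizations and genes at 0 could not be run for the same reason. Depth is unknown, so what it limits cannot be stated.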

Other observations

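All gene groups and tests in this part, and all genes named in it that the naming rule does not give, were chosen after the lists and their values had been seen. Only the tests of exonic length and of TEC models by position inside genes were set before their own results were seen, the latter once the result for other non-coding models was known. Small nuclear and nucleolar RNA genes were the 1 added group of 7 whose direction differed from the other listed genes, with 15 lower and 0 higher (two-sided Fisher's exact test, p = 0.00175, adjusted p = 0.0122 over the 7 groups). The group pools the snoRNA and snRNA types after both were seen to be all lower, and neither passed alone (adjusted p = 0.199 and 0.332, Fisher's exact test). Its members are not independent: Gm24265 and Gm24407 lie 654 bp apart, and close copies can share reads. Besides Snord17, the authors' deposited table listed the U3 RNA gene Rnu3a at -2.89, the U8 RNA gene Snord118 at -1.80 and Snord15a at -1.51. The RNA component gene of telomerase, Terc, was at -1.55 and the 7SK RNA gene Rn7sk at -2.24 in the same authors' deposited table, outside this group. Both are of the misc_RNA type, which had 4 lower and 2 higher genes, among the latter Gm27403, of 214 bases, at 7.33 in the authors' deposited table.

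Homeobox genes were lower in 9 cases and higher in 7 (adjusted p = 0.809, Fisher's exact test). The lower ones included Lhx1, Lhx9, Hesx1 and Shox2, and the higher ones Six3, Six2 and Irx6. Cilium and sperm genes were 11 lower, among them Cfap61 and the axonemal dynein genes Dnah7c and Dnah10, and 7 higher, among them Dnah12, Tekt5 and Catsper2 (adjusted p = 0.809, Fisher's exact test). Neurotransmitter receptor subunits were 6 lower and 5 higher (adjusted p = 0.809, Fisher's exact test). Of the muscle acetylcholine receptor subunits, Chrnd at -2.20 and Chrng at -1.66 were lower and Chrne at 2.20 was higher in the authors' deposited tables. All 4 listed regulators of G protein signalling, Rgs8, Rgs5, Rgs7 and Rgs4, were lower (adjusted p = 0.707, Fisher's exact test). Collagens were 8 lower and 1 higher (adjusted p = 0.588, Fisher's exact test), and opposite-strand transcripts 10 lower and 4 higher (adjusted p = 0.809, Fisher's exact test).

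The higher genes piled up just under a value of 2. They numbered 46 from 1.8 to under 1.9, 100 from 1.9 to under 2 and 20 from 2 to under 2.1, while the lower genes had 84, 49 and 42. On either side of 2, the counts were 49 and 10 in higher protein-coding genes and 51 and 10 in other higher genes. A step in the authors' processing was not tested, since the tables hold only its outcome. Genes with few reads, whose ratios repeat, may give such peaks. The 99 genes just under 2 were not detectably shorter than the other 309 higher genes (median exonic length 1929 against 2195 bases, permutation p = 0.303). Exonic length does not give the number of reads, so this comparison cannot decide it and the explanation stays open. The lower genes had a peak of their own, with 75 genes from 1.65 to under 1.70 between 40 and 41 in the adjoining intervals, and no biological explanation was tested.

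For the small nuclear and nucleolar RNA genes, a candidate explanation is that short RNA was recovered less in the sh-Mrhl libraries. Genes of other types except TEC were compared by exonic length. Those under 500 bases were lower in 48.8% of cases, against 62.9% of longer ones (two-sided Fisher's exact test, p = 0.0136). This argues against a loss of short annotated genes among these other types only. These types were pooled, so length was not separated from gene type. The test holds no small nuclear or nucleolar RNA genes, and annotated length need not be the length of the RNA recovered. A loss particular to such small RNA was therefore not tested. An effect of Mrhl knockdown on these RNAs stays open as an untested hypothesis, and so do differences between libraries, for which the tables hold no values.

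For the excess of TEC models among lower genes, neither of 2 technical explanations was settled. More genomic DNA in the scrambled libraries may raise processed pseudogenes there too, and these were 58.1% lower against 62.7% of protein-coding genes (Fisher's exact test, p = 0.283), which does not decide it. They were lower less often than the TEC models themselves, at 79.0% (Fisher's exact test, p = 0.000391). Nor did they show an excess over all other listed genes, of which 64.8% were lower. TEC models were singled out for their high share, and reads from parent genes would dilute such an effect in pseudogenes, so that genomic DNA is not excluded. More unspliced pre-mRNA in the scrambled libraries stays open as well: TEC models inside a protein-coding gene on its strand were 83.3% lower, against 61.9% of those outside (Fisher's exact test, p = 0.0654), and other non-coding models 65.0% against 58.0% (p = 0.487, Fisher's exact test). An effect of Mrhl knockdown stays open as well, untested.

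The 12 gene lists without a listed member together hold 984 annotated genes. Over all annotated protein-coding symbols 549 of 21924, or 2.50%, were listed. Among the lists with a listed member, the share ran from 0.69% for olfactory and vomeronasal receptors to 10.71% for the 2-cell-like list, and it was 31.58% for the lineage transcription factors, a list drawn up from what was known of the study. The annotated genes are not the genes the authors tested, so these shares are a description and not an enrichment test. Tex16 was in both tables, at -1.87 in the lower and 1.81 in the higher of the authors' deposited tables.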
